A study of Mus musculus with 4 samples.

How the data were processed

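Expression was measured in total RNA from spleens of female mice, 2 samples from Nrf2 knockout animals and 2 from wild-type littermates, 5 months old. Per the labels, animals of both genotypes came from interbred heterozygotes, and the knockout and wild-type parents had different mixed strain backgrounds. The deposited values are 1-colour probe-set intensities on a linear scale, 1 value for each of 12488 probe sets in each array. The software, its version and the scaling step used by the authors are not given in the sources used here. The deposited intensities had nearly equal 2% trimmed means, from 2501.5 to 2502.0 over the 4 arrays, from which a scaling to a common mean before deposit was inferred. Array medians were 848.6 and 854.6 for knockout replicates 1 and 2 and 798.6 and 837.2 for wild-type replicates 1 and 2. The 10 brightest probe sets held 3.32%, 3.80%, 6.07% and 3.10% of the signal in the same order. No 2 arrays held identical values.

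Because the trimmed means lay within 10% of each other, the intensities were used as deposited, without further scaling. Values below the pooled 25th percentile of the 4 arrays, an intensity of 185, were raised to that floor, and log2 was taken. A fold difference is on this scale, which understates the difference of dim genes. Where both arrays of a group lay below the floor, the fold is given as at least that value. The 66 control probe sets were left out, which left 12422, and the 7453 whose mean lay above the 40th percentile of all means were tested. Gene symbols came from the platform annotation and were updated through gene identifiers. Of the 12422, 10833 had 1 symbol, 396 several and 1193 none, and 10817 of those with 1 symbol matched the reference gene table by identifier. Among the tested probe sets these numbers were 6703, 270 and 480, covering 5705 genes. No gene was named from a probe set with several symbols.

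Knockout and wild type were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend (5.88 prior degrees of freedom), and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. All tests are two-sided. The median standard error was 0.46 on the log2 scale, with which a difference of 1.06 would reach an unadjusted p of 0.05. Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, on the brightest probe set of each gene, with an estimated correlation and fry as alternatives and adjustment over the 29 lists. For each list the number of members passing was also counted with adjustment over the list alone. Lists share some genes: 6 of the Nrf2 target genes, 1 of the erythroid, 1 of the platelet and 1 of the B cell genes tested belong to another list, and none of the pancreas or neutrophil genes. Gene positions relative to Nfe2l2 were taken from the GRCm38.p6 reference gene table, only to find which genes neighbour it, and shares within 20 Mb were compared with Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

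The genes named were set by a rule. It took the Nfe2l2 probe sets, and up to 12 genes in each direction with the largest difference among those with an adjusted p under 0.05 and separate groups, filled to 8 by the smallest p among those with an unadjusted p under 0.05. It also took up to 4 members of each list with the smallest p, and 7 well-known Nrf2 targets where measured. From the list members a part is named here. The groups, the tests, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives covered scaling, floor, filter, variance model, replicate block, array left out, cross-hybridising probe sets, threshold, list test and distance from Nfe2l2. Array weights and the removal of pancreas probe sets, with and without amylase, were added after seeing the data.

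The procedure was tested on simulated data with 200 of 7453 probe sets changed. It recovered 5.40% of those changed 2-fold, 64.5% of those changed 4-fold and 100% of those changed 16-fold or 64-fold, and 7.76% of the calls were false. For gene lists over 5705 genes, a shift of the neutrophil list by 0.8 on the log2 scale was recovered in 100% of 50 simulations, and 5.93% of unmoved lists had an unadjusted p under 0.05. In the simulation genes vary independently, while the neutrophil list had an estimated correlation of 0.58 in the data. The simulated arrays also had equal spread, while the array weights were 2.08 for each knockout array and 0.48 for each wild-type array. These rates may therefore not hold for the data.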

Results

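Spleens of female mice lacking the transcription factor Nrf2, which induces genes of detoxification and antioxidant defence, were compared with spleens of wild-type littermates. Total RNA was measured on 4 expression arrays, 2 knockout and 2 wild type, from animals 5 months old, an age that the labels place before severe autoimmune disease. Each array held 12488 probe sets, and 7453 were bright enough to test. The labels do not say whether an array holds RNA of 1 mouse or of a pool, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

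The first question was how far the arrays of a genotype resembled each other. Across tested probe sets, which are not independent replicates, Pearson's r was 0.938 between the knockout arrays. Knockout replicates 1 and 2 correlated with wild-type replicate 2 at 0.941 and 0.947. Wild-type replicate 1 stood apart, with r between 0.849 and 0.851 against the other 3 arrays. In that array 15.4% of tested probe sets lay more than 2-fold outside the range of the other 3, against 1.84% and 0.738% for knockout replicates 1 and 2 and 1.09% for wild-type replicate 2. The ratio of 3' to 5' signal of the Gapdh control, a measure of RNA and labelling quality, was 88.3 in wild-type replicate 1, 8.07 in wild-type replicate 2, 25.5 in knockout replicate 1 and 34.8 in knockout replicate 2. The same ratio for the beta-actin control was 14.4, 8.86, 19.3 and 16.1 in that order, so by beta-actin wild-type replicate 1 was not the extreme array. Both ratios were lowest in wild-type replicate 2, so knockout values set against that array alone also differ in this measure.

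The targeted gene was far lower in both knockout arrays. Nfe2l2, which encodes Nrf2, read 202 and 178.6 in knockout spleen against 3537 and 6321 in wild-type spleen. The difference was -4.61 on the log2 scale (SE 0.47, 95% confidence interval -5.69 to -3.53, n = 2 per group, limma adjusted p = 0.0199), a 24.4-fold lower level with values below the floor of 185 raised to it. The labels do not say whether this probe set lies in the deleted part of the gene. Its adjusted p was 0.143 without wild-type replicate 1 and 0.0583 without wild-type replicate 2, with differences of -5.03 and -4.19.

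Of the 7453 probe sets, 4 had an adjusted p under 0.05 and all 4 were lower in knockout spleen. Aass, a mitochondrial enzyme of lysine breakdown, fell furthest among those with a single gene name, from 15073 and 29022 in the wild-type arrays to 266.6 and 93.2 in the knockout arrays. Its log2 difference was -6.56 (SE 0.47, adjusted p = 0.00550), a 94.1-fold lower level. The other 2, beside Nfe2l2, were probe sets assigned to 6 and 5 genes of the pancreatic amylase family, which cannot be told from each other here. The first read 42.8 and 6.4 in knockout against 54968 and 14955 in wild-type spleen, at least 155-fold lower (adjusted p = 0.00726), since both knockout values lay below the floor. The second read 226.7 and 259.7 against 78338 and 19907, a 163-fold lower level (adjusted p = 0.00726). An unadjusted p under 0.05 was reached by 130 probe sets, 58 higher and 72 lower, where 373 would be so by chance. With each array centred on its median, 6 passed, 1 higher and 5 lower. The count of 4 was 0 without the filter on dim probe sets, 10 without knockout replicate 1, 13 without knockout replicate 2 and 2 without the probe sets of amylase and of the exocrine pancreas list.

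**Figure D1:**
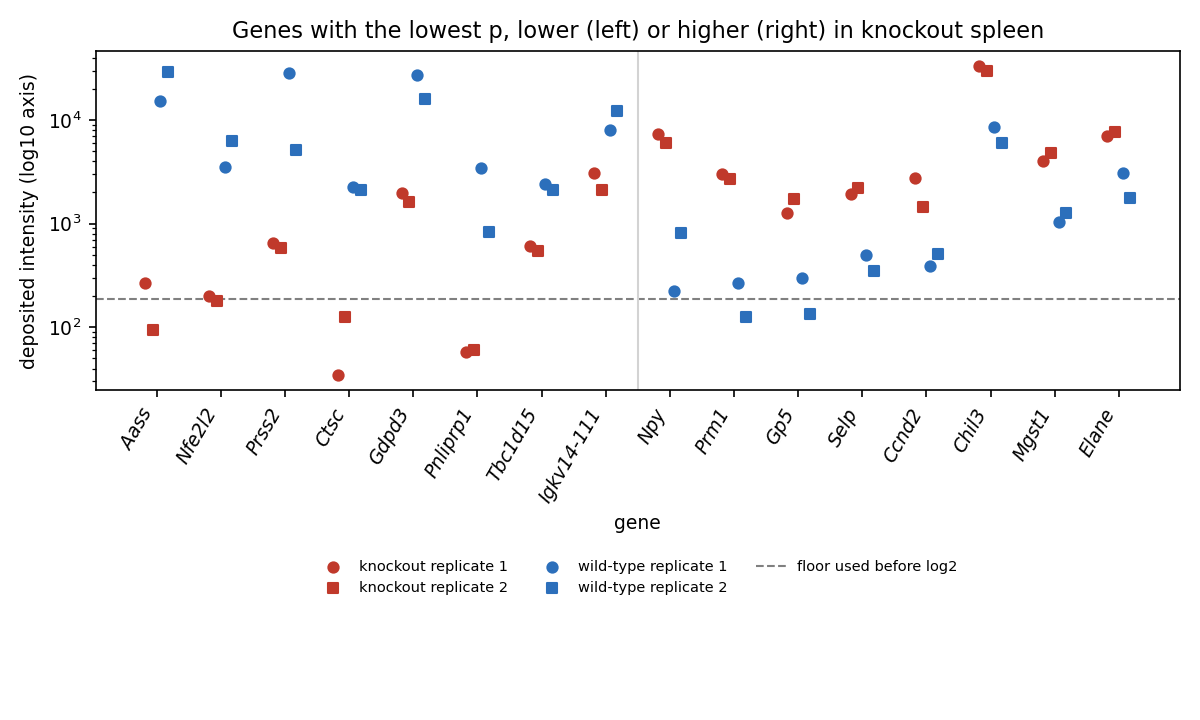
Deposited intensity on a log10 axis for the genes with the smallest p in each direction, among probe sets with 1 gene symbol and separate groups. There is 1 point per array, knockout in red and wild type in blue, and the floor is a dashed line. Both amylase probe sets passed but are not plotted, since each is assigned to several genes. Nfe2l2 reads 202 and 178.6 in the knockout arrays against 3537 and 6321 in the wild-type arrays, and only Aass and Nfe2l2 have an adjusted p under 0.05 among the genes plotted.

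Several other genes separated the genotypes without passing the threshold in the fit of all 4 arrays. Gdpd3, a lysophospholipase D, read 1994 and 1621 in knockout against 26988 and 15836 in wild-type spleen (log2 -3.52, SE 0.44, adjusted p = 0.0560). The lysosomal protease gene Ctsc was measured by 3 probe sets that differed from each other. One read 34.6 and 124.4 in knockout against 2271 and 2092 in wild-type spleen, at least 11.8-fold lower (adjusted p = 0.0680), and another read 365 and 322.9 against 1939 and 4241 (adjusted p = 0.264). The remaining Ctsc probe set differed by 0.21 on the log2 scale (SE 0.47, adjusted p = 0.992). Tbc1d15, a GTPase-activating protein gene, had a difference of -1.97 (adjusted p = 0.610), while its other probe set gave -0.16. The immunoglobulin kappa variable gene Igkv14-111 gave -1.95 (adjusted p = 0.764), and its 2 other probe sets gave -0.30 and -0.39 (adjusted p = 0.992 for both). With 1 array left out, the difference ranged from -3.91 to -3.14 for Gdpd3 and from -3.61 to -3.50 for the first Ctsc probe set. Gdpd3 passed with median centring, the 40th percentile floor, a pseudocount and array weights (adjusted p = 0.0280 to 0.0423). The first Ctsc probe set passed with a pseudocount and without an intensity trend (0.0393 and 0.0386). Both, with Tbc1d15 and Igkv14-111, passed with the replicate number as a block, though the labels do not pair samples by it.

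In the other direction, the protamine gene Prm1, a sperm chromatin protein, read 3000.5 and 2700 in knockout against 265.3 and 126 in wild-type spleen (log2 3.68, SE 0.46, adjusted p = 0.0560). Its probe set is one whose name marks possible cross-hybridisation, and no second Prm1 probe set was tested. The same mark is carried by the first Ctsc probe set, 1 of the amylase probe sets and the Prss2 probe set described below, among others. The name of the other amylase probe set carries a different mark, which was grouped with these where cross-hybridising probe sets were left out. Npy, which encodes neuropeptide Y, read 7261 and 5933 against 225.8 and 814.5 (log2 3.94, SE 0.61, adjusted p = 0.193). Ccnd2, encoding cyclin D2, differed by 2.16 (SE 0.49, adjusted p = 0.816). With 1 array left out, the difference ranged from 3.01 to 4.86 for Npy and from 3.42 to 3.94 for Prm1. Npy passed with the 40th percentile floor (adjusted p = 0.0404). Prm1 passed with median centring, with a pseudocount and without an intensity trend (0.0386 to 0.0483). Prm1, Npy and Ccnd2 passed with the replicate number as a block, though the labels do not pair samples by it.

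The next question was whether genes known to be driven by Nrf2 were lower without it. Of 27 tested members of the list of Nrf2 target genes, 9 measured higher and 18 lower in knockout spleen, and none passed the threshold over all probe sets. Without knockout replicate 2, 14 measured higher and 13 lower. Adjusted over the list alone, 1 passed, and it was higher: Mgst1, a microsomal glutathione transferase, read 4033 and 4785 in knockout against 1038 and 1271 in wild-type spleen (log2 1.94, SE 0.39, adjusted p = 0.0315 over the list alone and 0.543 over all probe sets). The adjusted p of Mgst1 over all probe sets was 0.0271 with the replicate number as a block, though the labels do not pair samples by it. No member passed over the list alone without knockout replicate 1, knockout replicate 2 or wild-type replicate 1, and 3 passed, all higher, without wild-type replicate 2. Ephx1, microsomal epoxide hydrolase, differed by -0.54 and Cat, catalase, by -0.46, with its other probe set at 0.84. The glutathione synthesis genes Gclc and Gclm differed by 0.25 and -0.21, the haem oxygenase gene Hmox1 by 0.81, the thioredoxin reductase gene Txnrd1 by 0.46 and the glutathione transferase gene Gstm1 by -0.19, each with an adjusted p of 0.992 or 0.993. The other Gstm1 probe set gave 0.03 (adjusted p = 0.997). Hmox1 was set apart by wild-type replicate 1, at 4840 against 19357, 25098 and 32609 in knockout replicates 1 and 2 and wild-type replicate 2. Nqo1, a quinone reductase often used as a readout of Nrf2, was too dim to test. It read 156.7 and 241.2 in knockout against 378.8 and 261.9 in wild-type spleen on 1 of its 2 probe sets. On the other it read 38.6 and 293.5 against 164.4 and 362.6, so the genotypes overlapped there. The list's median difference was -0.06 and its mean 0.02, and the camera test found it lower relative to all genes with an adjusted p of 0.785. The smaller lists of pentose phosphate and NADPH supply genes (median 0.09) and of peroxide and superoxide enzymes (median -0.06) had adjusted p of 0.863 and 0.266, and the peroxide and superoxide list was lower with an adjusted p of 0.0203 without knockout replicate 2.

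Of 29 gene lists fixed before the data were examined, 10 passed camera with a preset correlation of 0.01, 3 higher and 7 lower in knockout spleen. With an estimated correlation between genes none of the 29 passed (adjusted p = 0.676 for each of these 10), and fry, which tests whether a list moves one way on balance, also gave 0. With 2 arrays per group a pass with an estimated correlation was hardly attainable. The lowest unadjusted camera p was 0.137, for the pancreas list, which had 2.6e-13 at the preset correlation. The preset 0.01 lay far below some estimates, 0.72 for pancreas and 0.88 for ribosomal genes, so its p-values may be too small. Without wild-type replicate 1 the count was 5, and without wild-type replicate 2 it was 3. No member of these lists passed the threshold over all probe sets in the fit of all 4 arrays. Prss2, a pancreas gene, differed by -5.53 to -3.04 with 1 array left out. With the replicate number as a block, Prss2, Pnliprp1, Cel, Cela2a, Chil3, Selp, Gp5, Urod and Alb were among those that passed. The labels do not pair samples by that number, so this block has no stated basis.

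Genes of the exocrine pancreas, the digestive enzyme tissue that lies beside the spleen, were lower in knockout spleen as a list. Of 14 tested members, 11 measured lower, with a median difference of -1.82 (camera adjusted p = 7.6e-12, adjusted p = 0.676 with an estimated correlation). Adjusted over the list alone, 5 were lower and 0 higher, against 4 lower and 2 higher without wild-type replicate 1, 11 lower without wild-type replicate 2 and 8 lower without knockout replicate 2. Prss2, encoding a trypsinogen, read 653.1 and 586.9 in knockout against 28520 and 5090 in wild-type spleen (log2 -4.28, SE 0.73, adjusted p = 0.303 over all probe sets). The lipase-related gene Pnliprp1 read 58 and 60.3 against 3410 and 834.5, at least 9.10-fold lower (adjusted p = 0.764). The carboxyl ester lipase gene Cel read 1236 and 1481 against 9546 and 3186, and the elastase gene Cela2a 977.3 and 1107 against 7371 and 2348. The wild-type arrays differed from each other in this list by a median of 1.96, higher in wild-type replicate 1. The mean difference relative to all genes was -1.67, and it was -0.67 without wild-type replicate 1 (camera adjusted p = 0.00200) and -2.67 without wild-type replicate 2.

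Neutrophil and myeloid granule genes were higher in knockout spleen as a list, with 15 of 18 tested members measuring higher, a median difference of 1.001 and a camera adjusted p of 1.6e-06 (adjusted p = 0.676 with an estimated correlation). Adjusted over the list alone, 2 were higher and 0 lower. This count was 0 without either knockout array, 13 higher without wild-type replicate 1, and 4 higher and 2 lower without wild-type replicate 2. Chil3, a chitinase-like protein of myeloid cells, read 33018 and 29418 in knockout against 8527 and 6056 in wild-type spleen (log2 2.12, SE 0.42, adjusted p = 0.509 over all probe sets). Elane, neutrophil elastase, read 6950 and 7673 against 3092 and 1776 (log2 1.64, SE 0.43, adjusted p = 0.992). The gelatinase gene Mmp9 and the proteinase 3 gene Prtn3 differed by 1.39 and 1.51. The calprotectin gene S100a8, chosen after its values were seen, read 140070 and 148493 in knockout, 265039 in wild-type replicate 1 and 61459 in wild-type replicate 2. The call rested on wild-type replicate 2: the mean difference relative to all genes, 0.78, was 0.14 without it (camera adjusted p = 0.828, 11 of 18 higher, median 0.27) and 1.42 without wild-type replicate 1.

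**Figure D2:**
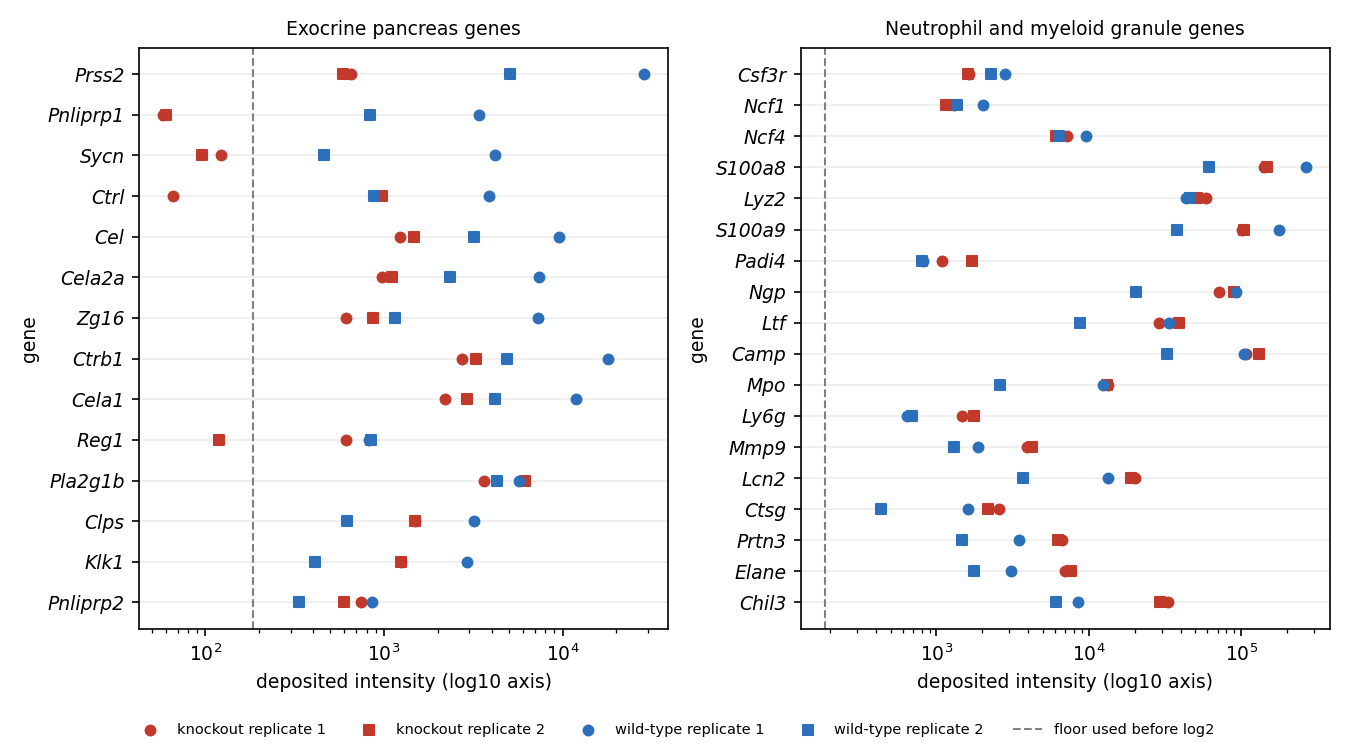
Deposited intensity on a log10 axis for each tested exocrine pancreas gene (left) and neutrophil and myeloid granule gene (right), with 1 point per array and the floor as a dashed line. Of the pancreas genes 11 of 14 measured lower in knockout spleen and of the neutrophil genes 15 of 18 measured higher, while S100a8 was highest in wild-type replicate 1 and lowest in wild-type replicate 2.

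Platelet and megakaryocyte genes measured higher in 9 of 10 cases, with a median difference of 0.23 and a mean of 0.61 (camera adjusted p = 0.0259, adjusted p = 0.676 with an estimated correlation). Adjusted over the list alone, 2 were higher, and 0 without knockout replicate 2. Selp, encoding P-selectin, read 1926 and 2214 in knockout against 502.1 and 348.1 in wild-type spleen (log2 2.30, SE 0.44, adjusted p = 0.493 over all probe sets), and the platelet glycoprotein gene Gp5 read 1261 and 1729 against 298.1 and 133.4 (log2 2.65, SE 0.52, adjusted p = 0.493). The list's adjusted p was 0.848 without wild-type replicate 2 and 0.0787 without knockout replicate 2. With only probe sets above the 60th percentile of mean intensity it was 0.913, and the mean relative to all genes moved from 0.55 to 0.02, against 0.93 without wild-type replicate 1 and 0.17 without wild-type replicate 2. In that last fit 5 of 10 measured higher, with a median of 0.10.

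Erythroid and haem synthesis genes measured lower in 19 of 22 cases, with a median of -0.52 (camera adjusted p = 0.00163, adjusted p = 0.676 with an estimated correlation), and 0 passed when adjusted over the list alone (4 lower without knockout replicate 2 and 1 lower without wild-type replicate 2). The haem synthesis gene Urod read 1762 and 4426 in knockout against 16356 and 7061 in wild-type spleen. Slc4a1, the red cell anion exchanger, read 5106 in knockout replicate 1, 30688 in knockout replicate 2, and 42541 and 26274 in the wild-type arrays. The blood group gene Rhd read 1936, 18537, 15224 and 14928 in the same order. Of the 22 genes, 21 were lower in knockout replicate 1 than in knockout replicate 2, by a median of 2.96-fold, and 19 were lower in knockout replicate 1 than in all 3 other arrays. The direction turned without that array, from -0.55 relative to all genes to 0.39 (camera adjusted p = 0.0145, 17 of 22 higher), and was -1.49 without knockout replicate 2. The list's adjusted p was 0.0526 and 0.191 without wild-type replicates 1 and 2, and 0.103 without the filter on dim probe sets.

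B cell genes measured lower in 13 of 19 cases, with a median of -0.39 (camera adjusted p = 0.0377, adjusted p = 0.676 with an estimated correlation). Fcer2a, the low-affinity IgE receptor CD23, read 4181 and 2792 in knockout against 11178 and 8495 in wild-type spleen (log2 -1.51, SE 0.42, adjusted p = 0.992 over all probe sets and 0.141 over the list alone). The pre-B-cell gene Vpreb3 differed by -0.99, with its other probe set at -0.57, and the antigen receptor gene Cd79b by -0.74. The B cell list passed in only 1 of the 4 fits with an array left out, that without knockout replicate 1, where the mean relative to all genes, -0.27, was -0.48, and it was -0.06 without knockout replicate 2. It also did not pass under quantile, median or loess scaling (adjusted p = 0.110, 0.0553 and 0.104), with the 40th percentile floor (0.0550), without the filter (0.103), with the replicate block (0.110), without cross-hybridising probe sets (0.0899) or with probe sets averaged (0.0605). T cell genes measured lower in 13 of 20 cases without passing (median -0.24, camera adjusted p = 0.0910), among them Cd8a at -0.94 and Cd3d at -1.08. The T cell list passed without knockout replicate 1 (adjusted p = 0.00916), with the 60th percentile filter (0.0435) and without cross-hybridising probe sets (0.0409). Without knockout replicate 2, 10 measured higher and 10 lower (median -0.02, adjusted p = 0.743), and the mean relative to all genes moved from -0.24 to -0.04, against -0.43 without knockout replicate 1.

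Cytoplasmic ribosomal protein genes measured lower in 21 of 23 cases (median -0.48, camera adjusted p = 8.2e-05) and respiratory chain genes in 32 of 44 (median -0.35, camera adjusted p = 0.00105), both with an adjusted p of 0.676 with an estimated correlation. Rpsa, a small-subunit protein gene, read 39558 and 40714 in knockout, 114806 in wild-type replicate 1 and 43927 in wild-type replicate 2, and the ATP synthase gene Atp5e read 8692, 8354, 19144 and 13641 in the same order. Without wild-type replicate 1 the means relative to all genes moved from -0.49 to 0.12 for ribosomal proteins and from -0.33 to -0.02 for the respiratory chain, neither passed, and 7 of 23 and 23 of 44 measured lower. Without wild-type replicate 2 they were -1.09 and -0.63. The ribosomal mean was -0.21 with quantile and -0.27 with loess scaling, and its adjusted p was 0.103 without the filter. Proteasome subunits (18 of 30 lower, median -0.22, camera adjusted p = 0.0451), among them Psmb5 at -0.87 on one probe set and 0.005 on the other, and immediate early genes (16 of 19 higher, median 0.29, camera adjusted p = 0.0377), among them Egr1 at 0.75, passed narrowly. Both had an adjusted p of 0.676 with an estimated correlation, the proteasome list passed in none of the 4 fits with an array left out, and the immediate early list passed only without knockout replicate 2. Neither passed with median centring, the 40th percentile floor, a pseudocount, the replicate block or without cross-hybridising probe sets, the proteasome list also not with quantile or loess scaling or probe sets averaged, and the immediate early list also not with no floor, without the filter, with the 60th percentile filter or with array weights. Hepatocyte genes measured lower in 4 of 5 cases (median -0.50, camera adjusted p = 0.0377, adjusted p = 0.676 with an estimated correlation). Alb, serum albumin, read 487.7 and 360 in knockout, 840.2 in wild-type replicate 1 and 4894 in wild-type replicate 2. The hepatocyte list did not pass without knockout replicate 2 or without wild-type replicate 2 (adjusted p = 0.0787 and 0.558), with the 40th percentile floor (0.0873) or without the filter (0.254).

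**Figure D3:**
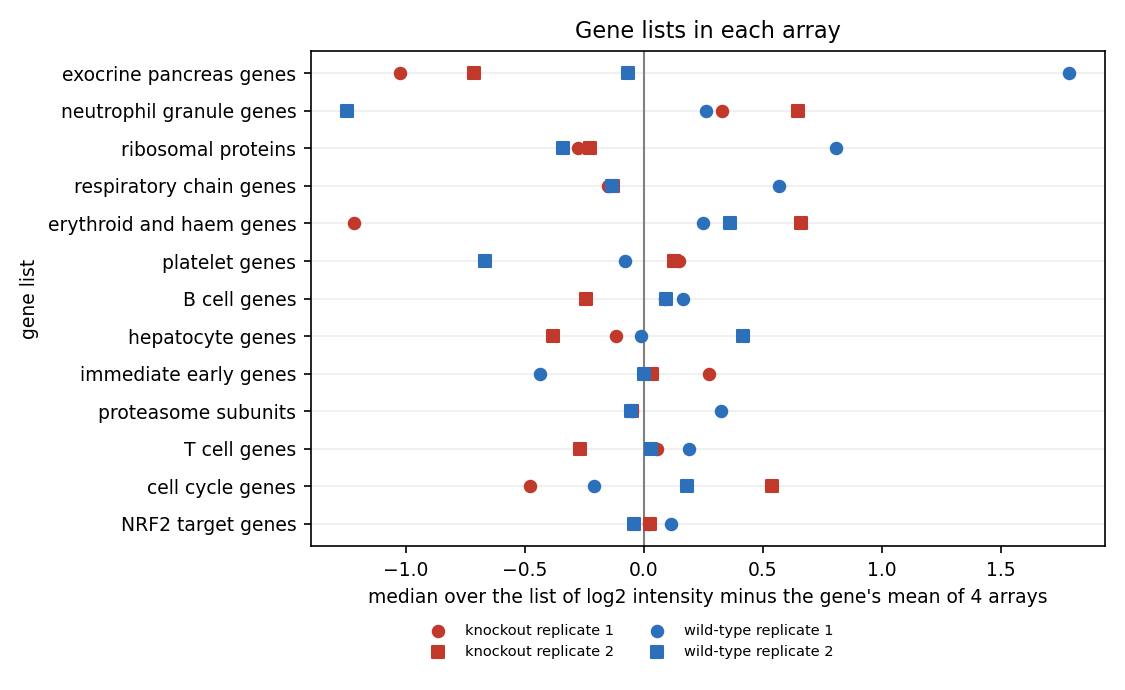
Median over each gene list of the log2 intensity minus the gene's mean over the 4 arrays, with 1 point per array, for the 10 lists that passed camera and for T cell, cell cycle and Nrf2 target genes. Erythroid genes were lowest in knockout replicate 1 at -1.22, pancreas genes highest in wild-type replicate 1 at 1.78, and neutrophil genes lowest in wild-type replicate 2 at -1.25.

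The other lists did not pass camera with the preset correlation. Their median differences were 0.20 for apoptosis and p53 response genes, 0.42 for endoplasmic reticulum stress genes, 0.56 for mast cell and basophil genes and 0.19 for stromal and smooth muscle genes (adjusted p = 0.137, 0.142, 0.151 and 0.285). Plasma cell and immunoglobulin genes had a median of 0.32 and interferon-induced genes of 0.03, both with an adjusted p of 0.494. Inflammatory cytokines and their receptors (median 0.19), heat shock proteins (0.05) and complement and Fc receptors (-0.06) each had an adjusted p of 0.621. Adipocyte genes had a median of 0.37 (adjusted p = 0.740), and cytotoxic and NK cell genes (-0.03), cell cycle genes (0.04) and red pulp macrophage genes (0.07) an adjusted p of 0.863. With an array left out, cell cycle genes passed higher without knockout replicate 1 (adjusted p = 0.00132) and lower without knockout replicate 2 (5.8e-05), endoplasmic reticulum stress and immunoglobulin genes passed higher without knockout replicate 2 (0.0145 and 0.0112), and mast cell genes higher without wild-type replicate 1 (0.00742). The median of each list in this paragraph turned, or moved by over 1.5 times, in at least 1 of the 4 fits with an array left out. Among the macrophage genes, Cd5l differed by -0.90 (adjusted p = 0.992). MHC class II genes had a median of 0.00068 and MHC class I genes of 0.07 (adjusted p = 0.909 and 0.992). For the Nrf2 target, heat shock and cytotoxic lists median and mean differed in sign. The camera direction, which is relative to all genes, was down for the pentose phosphate, cell cycle, heat shock and MHC class II lists, whose medians were above 0.

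The labels trace the knockout allele to a strain background other than that of the wild-type allele, so genes beside Nfe2l2 on chromosome 2 were examined for a local excess of differences. The mixed backgrounds of the parents may differ elsewhere in the genome too, and a strain difference there was not tested. Aass, Npy, Prss2, Igkv14-111, Mgst1 and Ccnd2 lie on chromosome 6, and Gdpd3 and Ctsc on chromosome 7. Prm1, Selp, Gp5, Chil3, Elane, Tbc1d15 and Pnliprp1 lie on other chromosomes. Within 20 Mb of Nfe2l2, 0 of 85 probe sets had an unadjusted p under 0.05 with separate groups, which allows a share of up to 3.53%. On other chromosomes 95 of 6166 did, or 1.54% (two-sided Fisher's exact test, p = 0.641, odds ratio 0 with a 95% interval up to 2.89). Without wild-type replicate 2 28 of 85 near Nfe2l2 (32.9%) and 1788 of 6166 on other chromosomes (29.0%) did (Fisher's exact test, p = 0.470).

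A rule of size that needs no variance estimate gave 131 probe sets at least 1.5-fold apart in all 4 knockout to wild-type pairs, 63 higher and 68 lower in knockout spleen. The other 2 ways to split the 4 arrays into pairs gave 249 and 171. At 2-fold the real split gave 45 and the other splits 48 and 41. The share of probe sets with separate groups was 26.4%, where chance gives 33.3%.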

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

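Array weights and the removal of pancreas probe sets, with and without amylase, were chosen after seeing the data; the other alternatives were planned. With 1 array left out, the lone array of a group is assumed to vary like the other group's. Each probe set's spread then rests on 1 pair of arrays and on the spread of other probe sets, so passes in these fits are uncertain. The 4 called probe sets remained called under each scaling, floor and variance model tried, under array weights, without the 14-gene pancreas list, which holds no amylase, and without the probe sets within 20 Mb of Nfe2l2 other than its own; 3 were shared with a filter at the 60th percentile, where Nfe2l2 was not tested, without wild-type replicate 1 and without wild-type replicate 2. The number called was 7 with a pseudocount, 0 without the dim filter, 2 without cross-hybridising probe sets (fewer were tested), 2, both lower, when amylase was removed along with the pancreas list, 7 at an adjusted p under 0.10 and 3 to 13 with an array left out, and 3 to 6 in the others except the replicate block. Those lower numbered 0 without the filter, 2 without cross-hybridising probe sets and 3 to 11 with an array left out. The number higher was 1 with median centring, the 40th percentile floor, a pseudocount, no trend and an adjusted p under 0.10, and 0 to 2 with an array left out. Replicate numbers are not said to pair samples, and the deviations of same-numbered arrays correlated at 0.04 over 2 pairs. With the replicate number as a block, 36 probe sets were called, 10 higher and 26 lower, all 4 among them. Nfe2l2 was -4.61 with an adjusted p of 0.713 without the filter, and -5.03 to -4.19 with an array left out. Among the 4969 dim probe sets none passed without the filter (lowest adjusted p 0.275), and intensities near the floor carry no order.

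Lists past camera numbered 6 with the 40th percentile floor, 5 without the filter, 0 with an estimated correlation, 0 with fry, 7 with the replicate block and 3 to 10 with an array left out. The pair count was 45 at 2-fold and 461 to 2757 with an array left out, where only 2 pairs remain. The median correlation of wild-type replicate 1 with the other arrays was 0.849, and 0.924 without the filter. The share near Nfe2l2 ranged from 0% to 32.9% with an array left out, against 1.10% to 29.0% on other chromosomes. Some list means relative to all genes, none past the threshold, turned: MHC class II genes to 0.0066 with quantile and 0.046 with loess scaling; MHC class I genes to 0.079 with quantile and 0.085 with loess scaling and 0.035 without the filter; adipocyte genes to -0.027 with no floor, -0.031 with a pseudocount, -0.017 without the filter and -0.068 without cross-hybridising probe sets. Pentose phosphate genes turned to -0.00037 with the 40th percentile floor, -0.0023 with a pseudocount, -0.015 with the 60th percentile filter, -0.0082 without cross-hybridising probe sets and -0.032 with probe sets averaged. At the 60th percentile filter Nrf2 targets turned to 0.020 and inflammatory genes to -0.070. With an array left out the ranges that crossed 0 were -0.15 to 0.045 for Nrf2 targets, -1.49 to 0.39 for erythroid, -0.23 to 0.53 for immunoglobulin, -0.080 to 0.34 for inflammatory, -0.51 to 0.43 for cell cycle, -0.21 to 0.016 for heat shock, -0.20 to 0.51 for adipocyte, -0.18 to 0.19 for pentose phosphate, -0.26 to 0.23 for MHC class II, -0.14 to 0.14 for MHC class I, -0.33 to 0.11 for complement, -0.11 to 0.32 for cytotoxic, -0.17 to 0.40 for macrophage, -1.09 to 0.12 for ribosomal and -0.052 to 0.59 for apoptosis genes. Single genes crossed 0 likewise: Gclm from -1.33 to 0.92, Gclc from -0.23 to 0.73, Hmox1 from -0.57 to 2.19, Txnrd1 from -0.051 to 0.96, Gstm1 from -0.47 to 0.099, Rhd from -2.96 to 0.30 and S100a8 from -0.88 to 1.23. The cause of these changes was not tested.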

Other observations

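The tests of unequal carry-over, of wild-type replicate 1 alone, of wild-type replicate 2 alone and of dilution, and the comparison of the knockout arrays with each other, were chosen only after the result was seen.

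The knockout arrays differed from each other in several cell-type lists at once. Erythroid genes were 2.96-fold lower and cell cycle genes 1.92-fold lower in knockout replicate 1 by the median, both at percentile 0 of 10000 random lists matched on mean expression. Immunoglobulin and plasma cell genes were 1.53-fold higher in knockout replicate 1, complement and Fc receptor genes 1.49-fold, B cell genes 1.36-fold, T cell genes 1.29-fold and interferon-induced genes 1.26-fold, at percentiles between 99.98 and 100. Neutrophil genes and pancreas genes did not stand out in this comparison, at percentiles of 44.8 and 26.9. These percentiles describe 2 arrays and are no test of mice.

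By the list median exocrine pancreas genes were higher in both wild-type arrays, although Pnliprp2, Clps, Pla2g1b and Klk1, 4 of 14 members, lay below the knockout mean in wild-type replicate 2. Against wild-type replicate 2 alone the list median of the knockout arrays was -0.89, at percentile 0 of matched random lists. The lower level was thus not confined to the comparison with wild-type replicate 1. Erythroid and cell cycle genes also lay at percentile 0 between the knockout arrays, so such a percentile does not measure the spread between arrays. The list mean stayed at -1.66 or below under 3 other scalings. Unequal carry-over of pancreas RNA into the wild-type samples may account for the pancreas difference: the list differed between the wild-type arrays by a median of 1.96, at percentile 100. Ribosomal protein genes differed between those arrays too, at percentile 99.99, so the divergence of wild-type replicate 1 can raise this value. Over the 10 members above the knockout mean in both, the excess in wild-type replicate 1 was a median of 5.97 times that in wild-type replicate 2 (from 0.948 for Reg1 to 15.8 for Zg16), and it was 3.68 and 3.97 times for the 2 amylase probe sets, and the genotype as a cause was not tested.

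Neutrophil and myeloid granule genes were higher in the knockout arrays than in wild-type replicate 2, with a median of 1.76 at percentile 100. The higher level was thus not confined to the comparison with wild-type replicate 1, though this percentile too does not measure the spread between arrays. Dilution of spleen RNA by pancreas RNA in the wild-type samples would raise B cell, T cell and macrophage genes alike. The median of those genes, -0.08, was not raised, and the neutrophil median exceeded it by 1.09, at percentile 100 of 10000 reassignments. The reassignments treat genes as independent, while the neutrophil genes had an estimated correlation of 0.58. The percentile therefore cannot decide on dilution. A low level in wild-type replicate 2 alone may account for part or all of the list. Against wild-type replicate 1 the median was 0.27, at a percentile of 91.1, inside the central 95% of random lists. Of 18 members, 11, Chil3 and Elane among them, had both wild-type arrays below both knockout arrays, and 2 had both above. Given a low wild-type replicate 2, this count turns on wild-type replicate 1, the array that stood apart. It therefore cannot show that the 11 fall outside this explanation. An effect of genotype stays open and untested.

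The Prm1 signal in both knockout arrays was not accompanied by other spermatid genes: 0 of 21 others on the array had both knockout arrays above the floor and at least 2-fold above both wild-type arrays, which argues against spermatid transcription in general. Its difference stayed at 3.58 or above under 3 other scalings. With array medians from 798.6 to 854.6, rescaling could hardly have moved a 12.8-fold difference, so this outcome was close to fixed in advance. What may remain are cross-hybridisation with another RNA, sequence carried by the targeted allele, or a difference of strain or genotype, none of which was tested.

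The 3 ways to split 4 arrays into pairs are too few for a share under 0.05. The real split called 4 probe sets and the highest of the others 0, with 130 at an unadjusted p under 0.05 in limma for the real split and 282 and 178 for the others.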
